A study of Homo sapiens with 6 samples.

How the data were processed

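RNA sequencing of 6 libraries from the HCT116 colorectal carcinoma line was used: NC cells and cells with the constructs shYAP1 or shYAP3, each in control medium and after 6 h of glucose deprivation. Per the labels' protocols, mRNA was taken from total RNA with oligo-dT beads, fragmented at random, copied to double-stranded cDNA and ligated to Illumina adapters. A strand setting, a read counter and an annotation were not given in the sources used here. Per the submitters' processing notes, Bowtie2, BWA and the human build hg19 were used, with no role, order or version stated.

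The deposited signal is a normalized value per gene, and the authors' scaling was not described. Within each library 100% of the values were whole multiples of the value of 1 read (tolerance 0.01 read), so whole reads could be recovered. 1 read was worth 0.0440 for NC, 0.0406 for shYAP1 and 0.0454 for shYAP3 in control medium, and 0.0532, 0.0581 and 0.0693 after deprivation, and the values of a library summed to between 841186 and 1172290. The table lists 14987 genes with an identifier and a symbol, 14508 of them protein coding, and 301 had no gene type. In 98.9% of cases it was in falling order of the deprived to control ratio of NC cells. No gene was at 0 in the NC control library, against 535 and 540 in the shYAP1 and shYAP3 control libraries and 753, 787 and 942 in the NC, shYAP1 and shYAP3 deprived libraries. Genes without reads in the NC control library are thus missing, and any that appeared only after deprivation or in shYAP cells could not be counted. The 10 highest genes took 7.79% to 10.25% of the reads of a library. A count of 0 allows up to 3 reads, worth 0.122 to 0.208, and this floor covers counting error only.

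Of the identifiers, 14661 (97.8%) matched a table of gene names and 14686 (98.0%) had a transcript length and GC content. The reference used for these was GRCh38 with GENCODE v29, another build than hg19, and no coordinates are given. Length and GC content are those of the longest transcript of each gene, which need not be the one expressed. Symbols are those of the deposited table, in which CYR61 is CCN1, CTGF is CCN2, IL8 is CXCL8 and MGEA5 is OGA.

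The design anticipated counts or normalized values. As the values are normalized, limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(value + 1) was the main test. Genes with a value of at least 1 in at least 2 libraries entered, 12263 in all. Fold changes are on the log2(value + 1) scale, which understates changes of low genes and can overstate or understate a difference between such changes. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The response over all cells and the knockdown over both media came from additive models of genotype and medium. The difference of the response between genotypes and the comparisons within a genotype or medium came from a model with 1 mean per genotype and medium, and the 2 constructs were compared in a model of construct and medium. The NC response has 1 library per medium and no test.

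The 32 gene lists hold 924 genes, of which 864 were found, and 29 lists had at least 5 tested members. They were tested with camera in limma at a preset correlation of 0.01, again with the correlation estimated, and with fry. With the correlation estimated, camera takes its degrees of freedom from the 6 libraries and not from the genes, so it has little power here. Medians in NC cells were placed among 10000 random lists. The lists were YAP and TEAD targets, the Hippo pathway, ATF4 targets, reticulum chaperones, tRNA synthetases, glycolysis, hypoxia-inducible targets, cholesterol, fatty acids, serine and one-carbon metabolism, gluconeogenesis, hexosamine, p53, NF-kB, interferon, NRF2, autophagy, heat shock, S phase, G2/M, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, the mitochondrial genome, histones, Wnt, immediate early genes, extracellular matrix, colorectal epithelium, and markers of fibroblasts, leukocytes and endothelium.

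Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took 18 genes chosen for the question, the 10 rising and 10 falling genes with the largest change among those past the threshold with a mean value of at least 1 and 1 sign in every construct, and the 4 members of each list with the smallest p. Where fewer than 5 passed, the 5 with the smallest p in each direction were named as not having passed. In the response, 2007 of 2018 higher and 1881 of 1918 lower genes met the rule on level and sign. Other genes are named where a count was at most 7, and were chosen after their values were seen. Some genes that the rule takes are not reported here.

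The alternatives were quantile normalization, no filter, a pseudocount of 0.1, no trend, a log2 threshold of 1, group contrasts, the construct as a block and leaving out each library. Chosen after seeing the data were scaling to listed reads, removal of each library's trend with GC content and length (splines of 5 degrees of freedom, 12107 genes), edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0 and limma-voom tests on the recovered reads, and gene lists under these settings, with the block and without the shYAP3 deprived library.

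Libraries of 1 construct come from the same construct's cells, so the construct pairs the libraries. The deviations of shYAP1 from shYAP3 in control and deprived medium correlated at 0.10 across genes (0.24 with GC content and length trends removed), and deviations from the mean of the medium at 0.46 for NC, 0.01 for shYAP1 and 0.33 for shYAP3. Reads of shYAP1 and shYAP3 differed by more than sampling noise, so none were counted as duplicates. The chi-square per gene was 8.94 (median 2.20) over 12253 genes in control medium. After deprivation it was 67.9 (median 11.6) over 12167 genes. Tests were run first on simulated data with 200 changed genes. For the response over all cells 84.7% of genes changed by log2 1 were recovered, for the knockdown over both media 87.8%, and for the difference of responses 10.1%, with 80.4% recovered there at log2 2. For the response in shYAP cells 62.6% were recovered at log2 1, for the knockdown in control medium 29.0%, under deprivation 24.0%, and for the difference between constructs 58.6%. These simulated genes were independent, with the same dispersion trend in all libraries and no GC content or length trends. The wider spread of the deprived shYAP pair was not simulated, so recovery in the real libraries may be lower. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.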

Results

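Messenger RNA was sequenced from HCT116, an established human colorectal carcinoma cell line, kept in control medium or deprived of glucose for 6 h. The study asked which part of the expression induced by glucose deprivation depends on YAP, the transcriptional coactivator that the Hippo kinases restrain and that acts through the TEAD DNA-binding factors. Cells labelled wild type (NC) gave 1 library in each medium. Cells in which YAP was knocked down gave 2 libraries in each medium, from the constructs shYAP1 and shYAP3. The reads listed per library were 20134048 for NC, 22161075 for shYAP1 and 18512413 for shYAP3 in control medium, and 19132907, 18353057 and 16912634 in the same order after deprivation. The deposited value of 1 read lay between 0.0406 and 0.0693, so that a count of 3 reads stood for 0.122 to 0.208. NC cells had no replicate in either medium and were assumed to vary as the shYAP libraries did. Each library came from cells of 1 construct in 1 medium, and the labels do not state replicate cultures. For single genes a p-value measures only the spread between these libraries, which mixes construct, culture and technical differences. A camera p-value sets a list against the other genes at an assumed correlation, and does not measure the spread between libraries alone.

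YAP1 (ENSG00000137693), the target of the knockdown, stood at 188 in NC cells in control medium, against 35.7 in shYAP1 and 38.2 in shYAP3 cells. After deprivation it stood at 154 in NC, 20.3 in shYAP1 and 18.2 in shYAP3 cells, so that all 4 shYAP libraries lay below both NC libraries. Over both media the shYAP cells held 0.162 times the NC level of YAP1, a log2 fold change of −2.63 (SE 0.17, limma adjusted p = 0.00082). Without the NC deprived library this fit reduces to the knockdown in control medium, where the log2 fold change of YAP1 was −2.32 and did not pass in limma. WWTR1 (ENSG00000018408), which encodes the YAP paralog TAZ, had a log2 fold change of −0.17 (limma adjusted p = 0.70). In the response to deprivation YAP1 fell by 0.70 (SE 0.16, limma adjusted p = 0.013), but not without the shYAP1 control library (adjusted p = 0.078) or the shYAP3 control library (adjusted p = 0.088).

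**Figure D1:**
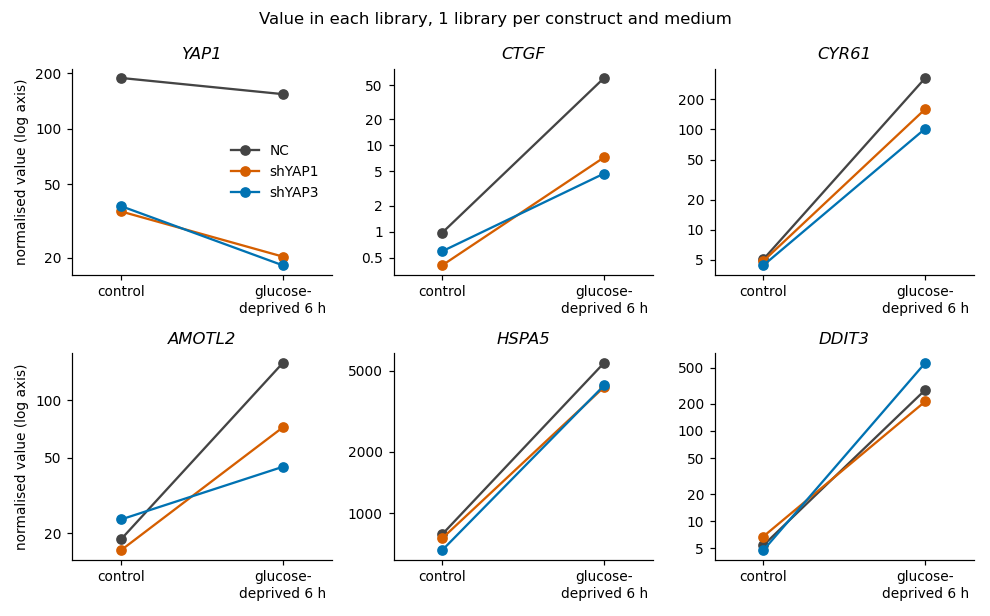
Deposited value (log axis) of YAP1, CTGF, CYR61, AMOTL2, HSPA5 and DDIT3 in control medium and after 6 h without glucose, with 1 point per library and lines joining the libraries of NC (grey), shYAP1 (orange) and shYAP3 (blue) cells. CTGF reached 60.5 in NC cells after deprivation, against 7.26 and 4.71 in shYAP1 and shYAP3 cells, whereas HSPA5 reached 5464, 4158 and 4234.

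Glucose deprivation raised stress transcription factors, immediate early genes and endoplasmic reticulum chaperones in NC, shYAP1 and shYAP3 cells alike in direction. DDIT3 (ENSG00000175197), which encodes the stress transcription factor CHOP, rose from 5.65 ± 1.02 to 354 ± 187 (SD, n = 3 libraries per medium), 49.2-fold on the log2(value + 1) scale. CYR61 (ENSG00000142871, now CCN1), a secreted matricellular protein and YAP target, rose from 4.78 ± 0.335 to 196 ± 116 (SD, n = 3). FOS (ENSG00000170345), JUN (ENSG00000177606), EGR1 and EGR2, immediate early transcription factors, rose 25.5-, 19.2-, 12.9- and 20.6-fold. ATF3 (ENSG00000162772), a stress-induced transcription factor, rose 15.9-fold from 9.08 ± 0.905 to 159 ± 13.1, and CHAC1, a glutathione-degrading enzyme, rose 13.8-fold (SD, n = 3). THBS1, which encodes thrombospondin, rose 14.7-fold. Among the genes that fell, the largest changes were in FP15737 (log2 −2.21), SOGA1 (−1.87), FZD4 (−1.83), NAT8L (−1.77), GPR157 (−1.76), PCF11 (−1.69), ZNF469 (−1.68), MAT2A (−1.66), RP11-1055B8.7 (−1.66) and RTN4RL1 (−1.65). FZD4, a Wnt receptor, fell from 12.8 ± 1.29 to 2.91 ± 0.447, and MAT2A, which makes S-adenosylmethionine, fell from 382 ± 32.6 to 120 ± 12.8 (SD, n = 3).

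Of 12263 genes tested with limma over both genotypes, 3936 changed after deprivation, 2018 higher and 1918 lower, and 630 of the changes were at least 2-fold, 328 higher and 302 lower. The adjusted p was 2.1e-05 for DDIT3 (log2 5.62, SE 0.31), 1.9e-05 for CYR61 (4.93, SE 0.26), 6.8e-06 for JUN (4.26, SE 0.17), 2.2e-06 for ATF3 (3.99, SE 0.13) and 0.00023 for MAT2A (−1.66, SE 0.14). The count was 1414 without the NC control library, 1141 without the shYAP1 control library, 1085 without the shYAP3 control library, 1427 without the NC deprived library, and 1607 as the mean of the NC and shYAP responses. Without an NC library the fit reduces to the response in shYAP cells, so those fits do not test the response of NC cells. Scaled to listed reads, which moved the median of all genes to −0.24 from 0.05, 749 genes were higher and 3820 lower. Of 129 named genes that passed, 73 also passed without each library in turn, DDIT3, CYR61, JUN, ATF3 and MAT2A among them, and 92 passed in every other setting. Of the genes named individually, MOB1B, STK3, YAP1, WWTR1, AXL, SLC2A3, PFKFB4, SLC16A3, VEGFA, STARD4, ACACA, FASN, UGDH, CSF1, FTH1, GINS1, CDC6, KIF20A, AURKA, CDC20, NOB1, POLR1A, RPL12, RPS13, NDUFB11, COX8A, MT-ND6, HIST1H1C, MYC, ZNRF3, CDX2, KRT8, EPCAM, COL1A1, HLA-DRA and CD68 did not pass without at least 1 library, with a highest limma adjusted p from 0.052 (NOB1, without the shYAP3 control library) to 0.22 (CD68, without the shYAP3 control library).

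The unfolded protein response and the amino acid stress program rose as groups. Of 41 targets of ATF4, the transcription factor of the integrated stress response, 35 rose and 0 fell (35 adjusted over the list alone), with a median log2 fold change of 1.05. SESN2, an inhibitor of mTORC1 signalling, rose 7.94-fold, TRIB3, a pseudokinase, 5.01-fold, and ASNS, asparagine synthetase, 4.30-fold. Of 34 endoplasmic reticulum chaperones and unfolded protein response genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 1.05. HSPA5 (ENSG00000044574), the reticulum chaperone BiP, rose 6.26-fold from 733 ± 66.9 to 4619 ± 733 (SD, n = 3), and HERPUD1, DNAJB9 and DNAJC3 rose 9.87-, 6.38- and 3.22-fold. Of 28 immediate early genes 27 rose and 0 fell (28 adjusted over the list alone), with a median of 1.90. DUSP5, a nuclear ERK phosphatase, rose 9.26-fold. Of 20 cytosolic tRNA synthetases 9 rose and 0 fell (11 adjusted over the list alone), with CARS 2.25-fold higher and SARS (log2 1.10) and AARS (1.03) among them.

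By camera in limma these groups stood above other genes at adjusted p = 2.4e-19 for ATF4 targets, 3.4e-13 for reticulum chaperones, 1.5e-20 for immediate early genes and 5.9e-05 for tRNA synthetases. None of the 4 calls held with the correlation between members estimated from the data, each at adjusted p = 0.51 with an estimated correlation. This does not show that correlation ended the calls, because that form of camera also rests on the few degrees of freedom of 6 libraries. The p53 targets had an estimated correlation of 0.0024, below the preset 0.01, and the same camera adjusted p = 0.51. Of 29 lists, 13 passed camera in this response, 0 passed with an estimated correlation and 11 passed fry, which asks whether the members of a list move on balance one way. Serine (fry adjusted p = 0.023), gluconeogenesis (0.0040) and histone genes (0.045) passed fry, higher, but not camera. Hypoxia-inducible targets (0.093), interferon-stimulated (0.081), matrix (0.061), ribosomal protein (0.061) and oxidative phosphorylation genes (0.19) passed camera but not fry.

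Genes that handle sugar and lipid moved in different directions. SLC2A3, a glucose transporter, rose 2.45-fold (limma adjusted p = 0.0067), whereas SLC2A1 (log2 0.42, adjusted p = 0.076) and HK2, a hexokinase (0.25, adjusted p = 0.25), did not pass in limma. ARRDC4, an arrestin family member that restrains glucose uptake, fell to 0.486 of its control level (limma adjusted p = 0.0068). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose 4.80-fold. PSAT1 (log2 1.14), PHGDH (1.02) and MTHFD2 (1.11) of serine and folate metabolism rose, while FASN (−0.95), the fatty acid synthase, ACACA (−0.64), acetyl-CoA carboxylase, and LSS (−1.09), lanosterol synthase, fell. SLC2A3 did not pass without either NC library (limma adjusted p = 0.056 for both), and FASN did not pass without either NC library or either shYAP control library (highest adjusted p = 0.095).

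As groups, 2 of 21 glycolysis genes rose and 2 fell (1 and 1 adjusted over the list alone), PFKFB4 (log2 −0.72) and SLC16A3 (−0.46) among the latter. Of 25 cholesterol genes 2 rose, STARD4 (0.70) among them, and 4 fell (2 and 4 adjusted over the list alone); of 15 fatty acid genes 0 rose and 5 fell (6 adjusted over the list alone). Serine and one-carbon genes had 4 of 15 higher and 0 lower, gluconeogenesis and transaminase genes 3 of 7 higher and 0 lower, GOT1 (1.13) among them (4 and 3 higher adjusted over the list alone). Hexosamine and glycosylation genes had 6 of 16 higher and 1 lower (7 and 1 adjusted over the list alone), with GMPPB (log2 1.04) and UGDH (0.71) higher and MGEA5 (−1.03, now OGA), which removes O-GlcNAc, lower. By camera none of these 6 lists stood apart, at adjusted p = 0.30, 0.27, 0.12, 0.093, 0.093 and 0.12 in the order given. With quantile normalization glycolysis (median −0.25 against 0.17), cholesterol (−0.16 against −0.05) and fatty acid genes passed lower (camera adjusted p = 0.020, 0.020 and 0.018), fatty acid genes passed also when scaled to listed reads (0.047), hexosamine genes passed with GC content and length trends removed (0.049), and gluconeogenesis genes passed without the shYAP3 deprived library (0.048). Scaled to listed reads, the medians of glycolysis (−0.13), serine (−0.14, against 0.13) and gluconeogenesis genes (−0.07, against 0.23) were negative. Of 22 hypoxia-inducible targets 8 rose and 2 fell (9 and 2 adjusted over the list alone), DDIT4 (1.16), ADM (1.01) and VEGFA (0.74) among the former (camera adjusted p = 0.018, and adjusted p = 0.65 with an estimated correlation). The hypoxia list did not pass with quantile normalization (camera adjusted p = 0.36). Scaled to listed reads, 5 hypoxia-inducible, 3 hexosamine, 1 glycolysis and 0 cholesterol genes rose.

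Ribosomal protein transcripts rose after deprivation, and a part of the nuclear respiratory chain transcripts did. All 78 cytosolic ribosomal protein genes rose (78 adjusted over the list alone), with a median log2 fold change of 0.48 in NC, 0.74 in shYAP1 and 1.47 in shYAP3 cells, and RPL10A rose 2.05-fold from 679, 749 and 662 to 1102, 1377 and 1929.5 in NC, shYAP1 and shYAP3 cells. RPS13 (log2 0.97) and RPL12 (0.81) rose too. These genes took 8.08%, 8.43% and 8.14% of listed reads in control medium and 9.84%, 12.01% and 15.4% after deprivation. Of 72 nuclear genes of oxidative phosphorylation 19 rose and 0 fell (12 adjusted over the list alone), NDUFB11 (0.71) and COX8A (0.52) among them, with a median of 0.45. Of 13 genes encoded in mitochondrial DNA 0 rose and 1, MT-ND6 (−0.54), fell (0 and 0 adjusted over the list alone).

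Camera gave adjusted p = 1.3e-19 for ribosomal proteins (adjusted p = 0.57 with an estimated correlation), 2.6e-07 for oxidative phosphorylation (adjusted p = 0.65 with an estimated correlation) and 0.76 for the mitochondrial genome. With quantile normalization 25 and scaled to listed reads 64 ribosomal protein genes rose (medians 0.33 and 0.58, against 0.89), as did 9 and 3 oxidative phosphorylation genes (0.32 and 0.14), whose median was 0.23 with GC content and length trends removed. With quantile normalization the mitochondrially encoded genes stood lower as a group (median −0.42, against 0.16; camera adjusted p = 0.00062), as they did with GC content and length trends removed (median −0.38, 0.021). Their median was −0.15 when scaled to listed reads. Without the shYAP3 deprived library the median of oxidative phosphorylation genes was 0.26 and that of tRNA synthetases 0.29, against 0.45 and 0.47. Many ribosomal protein genes have processed pseudogenes with which reads can be shared. The libraries differed in their dependence on transcript length and GC content, and the shYAP3 deprived library stood apart, with a median deviation from the gene mean of 0.44 among the shortest and −0.29 among the longest transcripts, each 10% of genes.

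**Figure D2:**
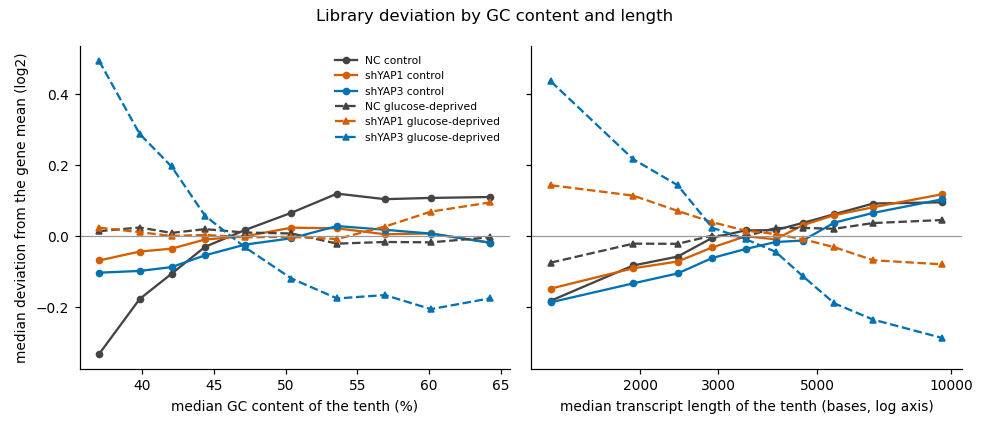
Median deviation from the gene mean (log2) in each library against GC content in percent (left) and transcript length in bases (right, log axis), for genes sorted into 10 classes of equal size. The NC control library ran from −0.33 to 0.11 and the shYAP3 deprived library from 0.49 to −0.17 between the lowest and highest GC class.

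Genes of the extracellular matrix and of Wnt signalling also moved. Of 33 matrix and invasion genes 14 rose and 3 fell (15 and 3 adjusted over the list alone), with PLAU, the urokinase plasminogen activator, 2.19-fold and LAMB3, a laminin chain, 3.39-fold higher (camera adjusted p = 0.0015, and adjusted p = 0.62 with an estimated correlation). Of 15 Wnt targets 2 rose and 6 fell (3 and 7 adjusted over the list alone). AXIN2 and ZNRF3, negative regulators of Wnt signalling, fell to 0.418 and 0.48 of their control level, while DKK1, a secreted Wnt antagonist, rose 3.87-fold and MYC 1.80-fold. The Wnt list did not pass (median −0.38, camera adjusted p = 0.11), and its median was −0.07 with GC content and length trends removed. Of 13 colorectal epithelial markers 4 rose, KRT8 (0.65, but −0.00631 with quantile normalization) and EPCAM (0.52) among them, and 1, CDX2 (−0.81), fell (6 and 1 adjusted over the list alone, 1 higher with quantile normalization and 0 scaled to listed reads; camera adjusted p = 0.11, and 0.027 without the shYAP3 deprived library). Among markers of other cell types, COL1A1 of fibroblasts fell (log2 −0.75, but −0.31 and not past the threshold with GC content and length trends removed) and HLA-DRA (0.84) and CD68 (0.71) of leukocytes rose. Of 6 fits without a single library COL1A1 passed in 2, HLA-DRA in 4 and CD68 in 1, and of 13 other settings they passed in 9, 12 and 7. CORO1A (0.48, limma adjusted p = 0.12, but 0.048 with the construct as a block) and the endothelial ESAM (0.28, adjusted p = 0.37) did not pass. With 1, 3 and 1 genes tested these marker lists were too small for camera, and they took at most 0.00134%, 0.0035% and 0.00079% of the listed reads of a library.

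YAP and TEAD targets rose in part. Of 17 tested, 7 rose and 3 fell (8 and 4 adjusted over the list alone). CTGF (ENSG00000118523, now CCN2) rose 8.70-fold, GADD45B 4.81-fold and AMOTL2 (ENSG00000114019), a negative regulator of YAP, 4.01-fold, AXL, a receptor tyrosine kinase, rose 1.94-fold, and FJX1 fell to 0.476 of its control level. The list did not pass (median 0.29, camera adjusted p = 0.18), but it passed without the shYAP3 deprived library (0.025), with GC content and length trends removed (0.045) and scaled to listed reads (0.018, with a median of −0.01). ANKRD1, a further YAP target, was below the filter and stood at 0.22 in NC, 0.041 in shYAP1 and 0.136 in shYAP3 cells in control medium and at 1.54, 0.116 and 0.901 after deprivation. Of 21 genes of the Hippo pathway 4 rose, STK3 (log2 0.87) among them, and 5 fell, MOB1B (−0.71) and YAP1 among them (4 and 5 adjusted over the list alone, 2 higher scaled to listed reads; camera adjusted p = 0.30). STK3 and MOB1B did not pass without either shYAP control library (limma adjusted p of at most 0.070 and 0.078). TXNIP was not analysed here.

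**Figure D3:**
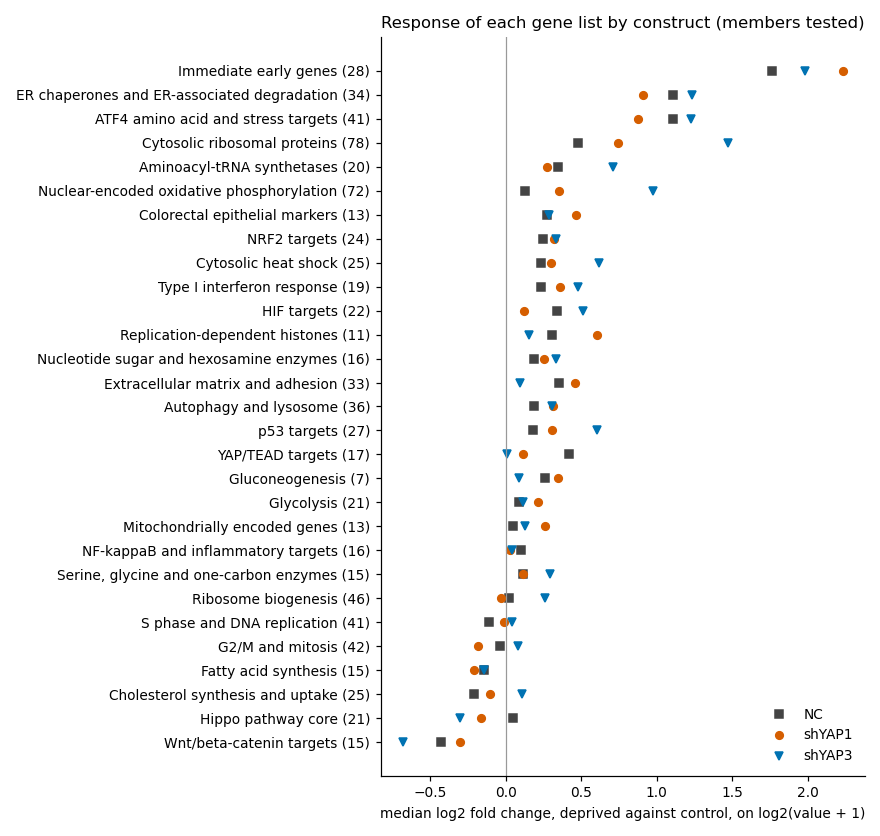
Median log2 fold change of deprived against control medium, on the log2(value + 1) scale, for each of 29 gene lists in NC (squares), shYAP1 (circles) and shYAP3 cells (triangles), with the number of members tested beside each list. The median of the YAP and TEAD targets was 0.42 in NC, 0.11 in shYAP1 and 0.01 in shYAP3 cells.

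In NC cells alone the response had no replicate and no test. Of 12059 genes with a value, 597 differed at least 2-fold, 352 higher and 245 lower, and with a pseudocount of 0.1 in place of 1 these were 825, 430 and 395. Medians of the ATF4 (1.11), reticulum chaperone (1.11), immediate early (1.76) and ribosomal protein lists (0.48) lay above all 10000 random lists matched on size and expression, and that of the YAP and TEAD targets (0.42) above 99.9% of them. Matrix genes (0.35), tRNA synthetases (0.34), histones (0.31), interferon-stimulated genes (0.24) and hypoxia-inducible targets (0.34) lay at percentiles 99.85, 99.0, 98.92, 98.51 and 98.48. At the low end the Wnt targets (−0.43), cholesterol (−0.21), S phase (−0.11), G2/M (−0.04) and fatty acid genes (−0.14) lay at percentiles 0.02, 0.01, 0.22, 0.89 and 1.2. In shYAP cells limma called 1412 genes, 689 higher and 723 lower. CYR61 rose 22.8-fold (adjusted p = 0.00091), CTGF 4.59-fold (0.0094), AMOTL2 2.81-fold (0.031), HSPA5 5.95-fold (0.0028), DDIT3 51.8-fold (0.0028) and ATF3 15.6-fold (0.00091).

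The count in shYAP cells was 3357 with the construct as a block (3255 with edgeR), 287 without the shYAP1 control library, 228 without the shYAP3 control library, 7812 without the shYAP1 deprived library and 5267 without the shYAP3 deprived library, and AMOTL2 did not pass without the shYAP1 control library (limma adjusted p = 0.080). Scaled to listed reads, 379 genes were higher and 2789 lower (median of all genes −0.29), and with no filter on low values 0 genes passed in limma (adjusted p = 0.10 for CYR61 and DDIT3), against 4444 of the filtered genes at an unadjusted p under 0.05, 1397 by edgeR, 1261 by limma-voom and 2521 by DESeq2. Across 12263 genes the responses correlated at Pearson 0.80 between NC and shYAP1, 0.76 between NC and shYAP3 and 0.76 between the shYAP constructs (Spearman 0.75, 0.74 and 0.73). These are correlations across genes, which are not independent replicates.

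Knockdown of YAP lowered 1 gene over both media by limma, YAP1 itself. The genes next to it by p did not pass (limma adjusted p = 0.58 for each): COL12A1, a fibril-associated collagen, stood at 67.6 in NC, 37.9 in shYAP1 and 42.3 in shYAP3 cells in control medium and at 78.1, 33.4 and 27.0 after deprivation, and RHOBTB3 at 111, 59.4 and 72.5 and then 121, 53.7 and 57.6. NRP1, a semaphorin and VEGF coreceptor, stood at 2.2 in NC, 6.29 in shYAP1 and 5.86 in shYAP3 cells, and at 2.18, 5.52 and 4.16 after deprivation. YAP and TEAD targets lay lower as a group in shYAP cells, with 15 of 17 log2 fold changes negative and a median of −0.64, −0.14 in control medium and −0.90 under deprivation. None of the 17 passed over all genes and 6 fell adjusted over the list alone, with CTGF at −1.78, ARHGEF17 at −0.80, CYR61 at −0.73, AMOTL2 at −0.69 and AXL at −0.64. Of 21 Hippo pathway genes 18 were negative (median −0.33), among them NF2 (−0.63) and LATS2 (−0.94) and PTPN14 (−0.84), which are also in the target list; 1, YAP1, fell over all genes and 3 fell adjusted over the list alone. Matrix genes included TAGLN (−1.13) and MYL9 (−0.76), of the contractile cytoskeleton, with 0 past the test over all genes and 3 lower adjusted over the list alone.

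By camera the YAP and TEAD targets (adjusted p = 5.5e-07) and the Hippo pathway (3.3e-07) lay below other genes, as did ATF4 targets (median −0.14, adjusted p = 0.0015), matrix genes (−0.25, 0.00039), fatty acid genes (−0.27, 0.0022) and cholesterol genes (−0.11, 0.014). The Hippo list holds YAP1, the target of the knockdown, and shares LATS2 and PTPN14 with the target list. Camera was not run without these members, so the Hippo call is not separate from the knockdown or from the target list. Ribosomal proteins (0.35, 3.0e-12) and oxidative phosphorylation genes (0.35, 2.7e-11) lay above, with medians of 0.04 and 0.06 in control medium and 0.67 and 0.61 under deprivation, and so did histones (0.26, 0.0048), p53 targets (0.15, 0.016), interferon-stimulated genes (0.15, 0.014), hypoxia-inducible targets (0.14, 0.025) and G2/M genes (0.15, 0.026). None of these 13 calls held with the correlation estimated (adjusted p = 0.72 with an estimated correlation, 0.73 for hypoxia-inducible targets and 0.78 for G2/M genes), and 0 lists passed fry. The hypoxia call was lost with quantile normalization (camera adjusted p = 0.080), the histone call with GC content and length trends removed (0.36), and the G2/M call with those trends removed (0.39), without the shYAP3 deprived library (0.30) or without the NC control library (0.32). The cholesterol call was also lost without the NC control library, where the fit reduces to the knockdown under deprivation (median −0.07). Heat shock genes, at camera adjusted p = 0.15 over both media, had a median of 0.26 under deprivation. Over all genes no member of the 13 lists but YAP1 passed, and adjusted over the list alone 2 histone genes and 1 hypoxia-inducible target were higher, while no member of the ATF4, fatty acid, cholesterol, ribosomal protein, oxidative phosphorylation, p53, interferon and G2/M lists passed. Without the shYAP3 deprived library the medians were −0.08 for matrix genes, 0.04 for interferon-stimulated genes, and 0.19 each for ribosomal proteins and oxidative phosphorylation. With trends removed they were −0.11, 0.07, 0.20 and 0.20 in that order, and 0.07 for p53 targets; with quantile normalization ribosomal proteins had 0.23. Without the shYAP3 deprived library reticulum chaperones (0.013), serine (0.028) and S phase genes (0.049) passed lower and autophagy genes (0.018) higher. With trends removed mitochondrially encoded genes (median −0.28, 0.0013), reticulum chaperones (0.015) and S phase genes (0.037) passed lower and autophagy genes (0.014) higher, and with quantile normalization reticulum chaperones (0.045) and immediate early genes (0.031) passed lower.

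The 1 call over both media compared with 898 genes at an unadjusted p under 0.05, 1 call each by edgeR and limma-voom and 7 by DESeq2 (YAP1, COL12A1, RHOBTB3, CYP24A1, FLNC, NRP1 and SERPINI1, named after their values were seen). Limma called 0 genes without the NC deprived library and 5 without the shYAP3 deprived library (YAP1, COL12A1, RHOBTB3, NRP1 and FLNC). In control medium limma called 0 genes, with 164 at an unadjusted p under 0.05, 0 by edgeR or limma-voom and 2 by DESeq2 (YAP1 and GOLGB1), and YAP1 had a log2 fold change of −2.32 (SE 0.21, limma adjusted p = 0.125), which passed with GC content and length trends removed (0.0025). Under deprivation limma called YAP1 alone (−2.94, SE 0.21, adjusted p = 0.025), and CTGF had −3.16 (SE 0.30, adjusted p = 0.077). CTGF passed scaled to listed reads (0.026) and with GC content and length trends removed (0.0064), whereas with no filter on low values YAP1 did not (limma adjusted p = 0.68). Leaving out a shYAP control library did not change these estimates under deprivation, since that library is not in this comparison. CTGF stayed at −3.16 and YAP1 at −2.94, with THBS1 at −1.94 and NUAK2 at −1.66. What changed was the spread, because a group left with 1 library no longer adds to it. In control medium YAP1 stood at −2.27 without the shYAP1 and at −2.37 without the shYAP3 control library.

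The test of whether the response to deprivation differed between shYAP and NC cells addressed the question of the study most directly. CTGF rose from 0.97 to 60.5 in NC cells but from 0.41 to 7.26 and from 0.59 to 4.71 in shYAP1 and shYAP3 cells, a log2 difference of −2.77 (SE 0.42). All control values of CTGF lay below the pseudocount of 1, which shrank the rises in shYAP cells more than that in NC cells. The scale therefore overstates the CTGF difference. THBS1 went from 5.1 to 204 in NC, from 3.77 to 63.3 in shYAP1 and from 5.32 to 43.5 in shYAP3 cells (−1.79, SE 0.43), AMOTL2 from 18.5 to 158, from 16.2 to 72.2 and from 23.6 to 44.7 (−1.53, SE 0.49), and CYR61 from 5.06 to 326, from 4.87 to 160 and from 4.41 to 102 (−1.24, SE 0.42). For NUAK2, a kinase of the AMPK family and a YAP target, the difference was −1.67. For the stress genes HSPA5, DDIT3 and ATF3 the differences were −0.22 (SE 0.36), 0.22 (SE 0.74) and −0.06 (SE 0.31). None of these differences passed in limma (adjusted p = 1 for each).

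Limma called 0 genes in this difference, with 111 at an unadjusted p under 0.05, 0 by edgeR or limma-voom and 1 by DESeq2 (RP11-542C16.2). With the construct as a block limma called 4 genes, CTGF (adjusted p = 1.4e-06), RP11-542C16.2 (2.1e-06), GCOM1 (0.024) and AL353354.2 (0.049). The blocked fit takes its spread only from how far the responses of shYAP1 and shYAP3 cells differ. No variation of NC cells enters it, so these p-values do not measure how firmly the NC response is known. RP11-542C16.2 stood at 0.968 in NC control cells and 0 in both shYAP control libraries, and at 0 in NC, 2.38 in shYAP1 and 1.80 in shYAP3 cells after deprivation. It is a low gene that, like the readthrough gene GCOM1 and AL353354.2, can share reads with overlapping genes, since no strand setting was stated. With a single shYAP library left out, a group kept 1 library and the spread came from the other shYAP pair alone. The CTGF difference was −2.86 without the shYAP1 control library. That of RP11-542C16.2 stayed at 2.60 without either shYAP control library.

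As a group, 16 of 17 YAP and TEAD targets had a more negative response in shYAP than in NC cells (median difference −0.65, camera adjusted p = 4.6e-13). Of these, 0 passed over all genes and 2 adjusted over the list alone. Of 21 Hippo pathway genes 18 were also more negative (−0.43, 5.4e-07), PTPN14 (−1.21) and LATS2 (−0.92) among them. The median response of the Hippo list was 0.05 in NC, −0.16 in shYAP1 and −0.30 in shYAP3 cells. All 78 ribosomal protein genes (median 0.62, 4.1e-25) and all 72 oxidative phosphorylation genes (0.54, 2.9e-20) had a more positive response in shYAP cells, with RPS9 at 0.85 and NDUFB2 at 0.99. With quantile normalization the medians were 0.26 and 0.45, and 68 and 71 members were positive. Without the shYAP3 deprived library the medians were −0.42 for YAP and TEAD targets, 0.37 for ribosomal proteins and 0.27 for oxidative phosphorylation, and with GC content and length trends removed they were −0.22 for the Hippo pathway, 0.38 for ribosomal proteins and 0.27 for oxidative phosphorylation. S phase genes (0.20, 33 of 41 positive, 0.0096) and cytosolic heat shock genes (0.20, 21 of 25 positive, 0.047) were also more positive. None of the 6 calls held with the correlation estimated (adjusted p = 0.77 with an estimated correlation), and 0 lists passed fry. With the construct as a block S phase (camera adjusted p = 0.078) and heat shock genes (0.092) did not pass, nor did they scaled to listed reads (0.057 for both) or with GC content and length trends removed (0.057 and 0.096), and heat shock genes did not pass with quantile normalization (0.64). ATF4 targets (median difference −0.11, camera adjusted p = 0.11), reticulum chaperones (−0.05, 0.47) and immediate early genes (0.02, 0.97) did not pass. ATF4 targets passed lower with quantile normalization (0.0036), trends removed (0.0095), scaling to listed reads (0.047) and without the shYAP3 deprived library (0.012), and reticulum chaperones passed lower with quantile normalization (0.031) and without that library (0.041). With quantile normalization matrix genes passed lower and histones higher (0.040 for both). Without the shYAP3 deprived library 13 lists passed, immediate early genes (0.39, adjusted p = 8.6e-11) and G2/M genes (−0.17, adjusted p = 5.1e-09) among them.

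The constructs shYAP1 and shYAP3 were compared with each other over both media. For YAP1 the difference of shYAP3 minus shYAP1 was −0.03 (SE 0.20, limma adjusted p = 0.97), and for CYR61, CTGF and AMOTL2 it was −0.38, −0.18 and −0.08. AMOTL2 stood at −0.91 without the shYAP3 control library and at 0.75 without the shYAP3 deprived library. DDIT3 differed by 0.49 (limma adjusted p = 0.70). Limma called 0 genes, with 843 at an unadjusted p under 0.05, 0 by edgeR or limma-voom and 1 by DESeq2 (PDCD4). The count was 3821 without the shYAP3 control library, 53 without the shYAP3 deprived library, 18 without the shYAP1 control library, 1 (SLX1B) without the shYAP1 deprived library, 13 without the NC control library and 19 without the NC deprived library.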

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

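All tests of explanations in this part, and the values that would exclude each explanation, were chosen after the results were seen, and those values were revised after a first set had been applied; the limma and camera tests of the difference were planned. Intervals are 95% bootstrap intervals over genes, which take genes as independent and leave out the spread between libraries.

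The response to glucose deprivation was more negative in shYAP than in NC cells for the YAP and TEAD targets (median difference −0.65) in camera, but not with the correlation estimated (adjusted p = 0.77 with an estimated correlation) or in fry (adjusted p = 0.98). A smaller difference of the same sign remained with GC content and length trends removed (−0.54 [−0.87, −0.24], camera adjusted p = 7.5e-15 at the preset correlation). Without the shYAP3 deprived library it was −0.42 [−0.86, −0.07]. The intervals take genes as independent, but the estimated correlation between members was 0.53. They therefore cannot exclude the trends or that library as the whole cause, and either may contribute. In shYAP against NC cells the targets stood at −0.14 [−0.31, 0.0088] in control medium and at −0.90 [−1.40, −0.51] under deprivation, and each value rests on a single NC library. A deviation of the NC control or of the NC deprived library cannot be told apart from an effect of YAP, because neither was measured again and the knockdown effect in either medium is not otherwise known. A need for YAP in the induction of CTGF, THBS1 and AMOTL2 may account for the pattern, as a hypothesis beside these open explanations.

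Camera also set ribosomal protein (median difference 0.62) and oxidative phosphorylation genes (0.54) higher in the response of shYAP cells, but neither call held with the correlation estimated (adjusted p = 0.77 with an estimated correlation) or in fry (adjusted p = 0.98). For ribosomal proteins the excess over 20 matched genes was 0.31 [0.23, 0.36]. Without the shYAP3 deprived library the median difference was 0.37 [0.34, 0.39]. It was 0.46 [0.37, 0.53] scaled to listed reads and 0.26 [0.19, 0.30] with quantile normalization, where 68 of 78 were positive. For oxidative phosphorylation these values were 0.22 [0.15, 0.32], 0.27 [0.25, 0.31], 0.38 [0.32, 0.41] and 0.45 [0.38, 0.52]. The differences left under both scalings argue against the scaling as the whole cause, though they were smaller there. Members moved together, with estimated correlations of 0.88 and 0.77 in the response over all cells, so the intervals are too narrow. The matched genes were the nearest ones, with no limit on distance. The trends and the shYAP3 deprived library therefore cannot be excluded as the whole cause. In shYAP against NC cells both lists stood at 0.0427 [0.012, 0.056] and 0.0614 [0.039, 0.090] in control medium and at 0.67 [0.55, 0.74] and 0.61 [0.55, 0.69] under deprivation. Each value rests on a single NC library, so that a deviation of the NC control or the NC deprived library cannot be told apart from an effect of YAP knockdown.

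Among genes whose response was more negative in shYAP cells at an unadjusted p under 0.05, 71 had a length and GC content, and they were long (median 9747 bases, against 3725 for all genes tested) and AT-rich (median GC content 40.2%, against 48.6%), beyond all of 10000 random draws, whereas 31 of the 38 with a more positive response had both values and were short (median 2034 bases) and GC-rich (56.5%). With trends removed 78.6% [73.2, 85.7] of their median difference was left (−0.76 of −0.97) and 51 of the 71 stayed at an unadjusted p under 0.05. In control medium these genes stood 0.60 [0.39, 0.75] higher in shYAP than in NC cells, and under deprivation at −0.45. The genes were picked by their difference, which keeps part of it whatever is removed, so neither value excludes the trends or a deviating NC control library, and either may account for the pattern. None of these genes passed the adjusted test, and no biological explanation was tested.

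For single genes the NC cells moved one way under deprivation and both shYAP constructs the other, and the limma test of the difference did not pass (adjusted p = 1 for each). With the construct as a block RP11-542C16.2 (adjusted p = 2.1e-06), GCOM1 (0.024) and AL353354.2 (0.049) passed in limma, and RP11-542C16.2 passed also with DESeq2 (0.0043). The blocked fit measures only the spread between the 2 shYAP responses, with no variation of NC cells. Without the shYAP1 deprived library the difference was −0.76 for COL12A1, −1.61 for DST, −1.56 for PTPN14 and 1.35 for NDUFB2. Without the shYAP3 deprived library it was −0.46, −1.37, −0.86 and 0.64 in that order. GCOM1 stood at 1.87 and 2.01, AL353354.2 at 1.88 and 1.79 and ZNF595 at 1.10 and 1.02 in these fits. With all libraries the differences were −0.36 for RHOBTB3, −0.61 for COL12A1, −1.49 for DST and −1.21 for PTPN14. They were 2.60 for RP11-542C16.2, 1.94 for GCOM1, 1.83 for AL353354.2, 1.06 for ZNF595 and 0.99 for NDUFB2. Camera at the preset correlation also called the difference for the Hippo pathway (median −0.43), cytosolic heat shock (0.20) and S phase genes (0.20), each at adjusted p = 0.77 with an estimated correlation. Heat shock and S phase genes did not pass with the construct as a block (0.092 and 0.078), scaled to listed reads (0.057 for both) or with trends removed (0.096 and 0.057).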

How the results depend on the processing

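Chosen after seeing the data were scaling to listed reads, removal of GC content and length trends, and edgeR, DESeq2 and limma-voom on recovered reads. So were gene lists under these settings, with the block and without the shYAP3 deprived library. The other settings were planned. The response over all cells (3936 genes) gave 630 genes at a log2 change of at least 1 and 1607 as the mean of the group contrasts, and 1085 to 5303 with single libraries left out; quantile normalization, no filter, a pseudocount of 0.1, no trend, the block, scaling, trend removal, edgeR, limma-voom and DESeq2 gave between 3382 and 5279. The knockdown over both media (1) gave 7 genes with DESeq2 and 0 to 5 with single libraries left out. The difference of responses (0 with limma) gave 4 with the replicate block on the construct, 1 with DESeq2 and 1 to 2739 with single libraries left out. The response in shYAP cells (1412) gave 0 with no filter, 773 at a log2 change of at least 1, 3357 with the replicate block, 3168 scaled to listed reads, 2823 with trends removed, 4298 with trends removed and the block, 3255 with edgeR and the block, 2521 with DESeq2 and 228 to 7812 with single libraries left out. The block brought 9 results of named genes past the threshold (MT-ND3 and CORO1A in the response over all cells, the 4 genes of the difference, and WWTR1, AXL and SLC2A3 in shYAP cells), ended the list calls of S phase and heat shock genes, and changed the call of no other named gene or list.

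The knockdown in control medium (0) gave 1 with trends removed, 2 with DESeq2 and 0 to 495 with single libraries left out. Under deprivation (1) it gave 0 with no filter, 2 scaled to listed reads, 2 with trends removed, 5 with DESeq2 (YAP1, CTGF, THBS1, COL12A1 and GCOM1) and 1 to 5723. The difference between constructs (0) gave 1 with quantile normalization (NEDD9), 3 scaled to listed reads (NEDD9, MSH5-SAPCD1 and SLX1B), 3 with trends removed (NEDD9, PDCD4 and PPP1CB), 1 with DESeq2 and 1 to 3821. No filter adds low genes to the adjustment. Without an NC library the additive fits reduce to the response in shYAP cells or to the knockdown in the remaining NC medium. Where a library was left out and an arm kept 1 sample, that sample was assumed to vary like the other groups. With 1 mean per genotype and medium, the spread then came from the other shYAP pair alone. The shYAP libraries differed less in control medium (chi-square per gene 8.94) than after deprivation (67.9). Calls and counts from such fits, here and above, depend on this spread and are not read as findings. The cause of the other shifts was not tested.

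Of the camera calls 0 held with an estimated correlation for the response, 0 for the knockdown and 0 for the difference, and fry gave 0 for the knockdown and 0 for the difference; 13 lists passed in the difference without the shYAP3 deprived library. FTH1 (−0.0235) and KRT8 (−0.00631) turned negative in the response with quantile normalization, and AMOTL2 between constructs ranged from −0.91 without the shYAP3 control library to 0.75 without the shYAP3 deprived library. Correlations of responses moved to 0.83 (NC and shYAP1, genes with a mean of at least 10), and with trends removed to 0.84 (NC and shYAP1) and 0.79 (shYAP1 and shYAP3). Of the results for named genes, quantile normalization kept direction and call in 445 and ended 9 calls, no filter ended 20, scaling to listed reads 19, trend removal 12, edgeR 2, limma-voom 1 (CD68 in the response) and the mean of group contrasts 30. Leaving out the NC control library ended 38, the NC deprived 37, the shYAP1 control 46, the shYAP3 control 50, the shYAP1 deprived 6 and the shYAP3 deprived library 0, and in the same order brought 0, 0, 5, 14, 92 and 43 past the threshold. Genes near the floor of 3 reads were limited by depth.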

Other observations

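Glucose deprivation also moved stress and clearance genes that the comparisons above do not cover. Of 27 p53 targets 13 rose and 3 fell (13 and 5 adjusted over the list alone), with GDF15, a stress-induced cytokine, 7.50-fold and PLK3, a stress-activated kinase, 3.92-fold higher (camera adjusted p = 0.013, and adjusted p = 0.51 with an estimated correlation). Of 36 autophagy and lysosome genes 11 rose and 1 fell (11 and 2 adjusted over the list alone), MAP1LC3B, the autophagosome protein LC3B, from 67.9 ± 4.48 to 204 ± 9.79 (SD, n = 3) and GABARAPL1 by 0.91 on the log2 scale (camera adjusted p = 0.0030, and adjusted p = 0.51 with an estimated correlation). Of 25 cytosolic heat shock genes 9 rose and 0 fell (12 adjusted over the list alone), with DNAJB1, a cochaperone of HSP70, 6.18-fold and HSPB1 2.12-fold higher (camera adjusted p = 0.00026, and adjusted p = 0.51 with an estimated correlation). Of 24 NRF2 targets 6 rose and 0 fell (6 adjusted over the list alone), SLC7A11, the cystine transporter and also an ATF4 target, 3.23-fold (camera adjusted p = 0.0040, and adjusted p = 0.55 with an estimated correlation). Of 19 interferon-stimulated genes 5 rose and 0 fell (5 adjusted over the list alone), ISG15 from 60.5, 67.3 and 70.5 to 101, 214 and 216 in NC, shYAP1 and shYAP3 cells, OASL by 1.31 and IRF7 by 1.08 on the log2 scale (camera adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation). Scaled to listed reads, which moved the median of all genes to −0.24, 6 p53 targets, 4 autophagy, 7 heat shock, 2 NRF2 and 3 interferon-stimulated genes rose. With quantile normalization heat shock (camera adjusted p = 0.074) and NRF2 targets (0.16) did not pass, and interferon-stimulated genes did not pass with GC content and length trends removed (0.053) or without the shYAP3 deprived library (0.10).

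Among genes of proliferation, 1 of 42 G2/M genes rose after deprivation and 5 fell (0 and 5 adjusted over the list alone), PLK1, a mitotic kinase, to 0.574 of its control level, and KIF20A (log2 −0.71), AURKA (−0.58) and CDC20 (−0.57) were among the genes that fell (camera adjusted p = 0.30). The G2/M list passed lower with quantile normalization (0.020), with GC content and length trends removed (0.0035) and without the shYAP3 deprived library (0.011). Of 41 S phase genes 6 rose, CDC6 (0.73) among them, and 4 fell, GINS1 (−0.72) among them (6 and 4 adjusted over the list alone; camera adjusted p = 0.99). Of 46 ribosome biogenesis genes 2 rose, NOB1 (0.81) among them, and 5 fell, POLR1A (−0.83), the largest subunit of RNA polymerase I, among them (2 and 3 adjusted over the list alone; camera adjusted p = 0.71). Scaled to listed reads 0 G2/M, 1 S phase, 1 NF-kB and 3 histone genes rose. The median of the ribosome biogenesis list was 0.08, but −0.05 with quantile normalization and −0.22 scaled to listed reads. Of 16 NF-kB targets 3 rose, IL8 2.61-fold, and 2 fell, CSF1 (−0.76) among them (3 and 2 adjusted over the list alone; camera adjusted p = 0.84). Of 11 histone genes 5 rose, HIST1H1C (0.61) among them, and 0 fell (5 adjusted over the list alone). Camera gave adjusted p = 0.12, but 0.021 with quantile normalization and 0.028 scaled to listed reads. With GC content and length trends removed the median was 0.03, against 0.34, at camera adjusted p = 0.91. Most histone mRNAs lack poly(A) tails and are poorly caught by oligo-dT beads, and their copies share reads.

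All tests in the rest of this part were chosen after the results were seen. The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real division by medium gave 3936 genes and the highest of the others 0, so that 1 of the 10 gave as many as the real one. The 3 other divisions that also part the libraries of every construct gave 0 each by limma. The other divisions leave the real response to medium in the spread, which by itself lowers their calls. Their 0 therefore does not show how many calls arise by chance.

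A smaller induction of all deprivation genes in shYAP cells was looked for as a hypothesis (intervals are 95% bootstrap over genes). The 300 genes that rose most in shYAP1 cells had a median response of 1.20 in NC and 1.34 in shYAP3 cells, a median NC minus shYAP3 difference of −0.0423 [−0.09, 0.02]. The 300 that rose most in shYAP3 cells had 0.99 in NC and 0.90 in shYAP1 cells, a median difference of −0.0246 [−0.10, 0.04]. Genes picked by their induction in shYAP cells leave out those whose induction needs YAP, so these values do not decide on the hypothesis.

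Across 12263 genes the knockdown effect in control medium and that under deprivation, which share no library, correlated at Pearson 0.46 and Spearman 0.49, and at 0.40 and 0.41 with GC content and length trends removed. The Pearson value of 0.46 is the same quantity as the correlation of NC deviations from the mean of the medium, and not separate evidence. It cannot tell a lasting difference of the NC cells from an effect of YAP knockdown. Genes are not independent replicates.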
